A study of Homo sapiens with 6 samples.

How the data were processed

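The study measured RNA from sorted NCI-H520 cells. Per the labels' protocols, cells were sorted into bins by their SIA-cIgG level and libraries were made with a NEBNext Ultra RNA kit for Illumina sequencing. Whether counting used the strand is not given in the sources used here. The submitters' processing notes name STAR 2.5.2b, Picard, SAMtools 0.1.18, GATK, HTSeq 0.5.4 and the build hg38, with no role or order. The authors deposited a single table for the whole series, whose name announces FPKM, fragments per kilobase of gene length scaled to the size of the library. Per the file headers, it also gives the chromosome, start, end, length in bases, type and name of each gene.

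The samples were grouped by their titles into 3 with high and 3 with low SIA-cIgG. The 6 value columns of the table are headed by running numbers that occur in no label of any sample. Matching them to samples would have rested on the order of the columns alone, so these 6 columns were not used in any step. The tests designed before the data were examined, a limma comparison of log2 FPKM values between the groups, tests of 43 gene lists and a check of replicate structure, were therefore not run. The depth per sample is unknown, and no group mean, error or p-value was computed. Of the rule for named genes, also set beforehand, the part that could be applied was the list of 18 genes taken from the study's title and the sorted marker, which are named whatever their values.

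What was computed uses only the annotation columns of the authors' table, which are properties of genes and carry no replicate error. This examination was chosen after the table had been seen. Gene identifiers were matched without version to GENCODE release 29 (GRCh38). List members were matched to rows by gene name. Failing that, a reference of current and older gene symbols was used, and then the name in GENCODE 29. For each matched gene the mean, median, shortest and longest transcript length and the merged length of all exons were computed from the comprehensive annotation. A listed length was called matching when it lay within 1% of a computed one. Shares of genes are given with 95% Wilson intervals where stated. They describe this annotation and treat genes as independent.

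For the 18 genes, exon bases in common with exons of another gene were counted on either strand. Every distinct stretch of 100 bases in their annotated transcripts was searched, in both orientations, in all GENCODE 29 transcripts of genes that do not overlap the gene itself. Only exact matches were counted, so stretches that differ at any base are not included. The read length is not given in the sources used here, so stretches of 50 and 150 bases were tried as alternatives, and introns and unannotated sequence were not searched. Positions are given as in the authors' table, counted from 1. For MET, SOX2, ITGA6, NANOG, ALDH1A1 and ST6GAL1 they differ from GENCODE 29 at one end. Computations used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1.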

Results

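RNA sequencing was performed on NCI-H520, an established human lung squamous carcinoma cell line, after its cells had been separated by flow cytometry according to their level of SIA-cIgG, the cancer-derived immunoglobulin G named in the study's title. The labels describe 6 samples in 2 groups, with 3 biological replicates sorted for high SIA-cIgG and 3 sorted for low SIA-cIgG. The comparison implied by this design is which genes differ in expression between cells with high and low SIA-cIgG, with the c-Met receptor, the transcription factor SOX2 and stemness genes in view from the title. The deposited expression table carries 6 value columns headed only by a running sample number. No title, description or characteristic of a sample contains such a name, so the columns were not matched to the high or the low group. The expression values in those columns were not analysed here, and no difference between the groups, no depth per sample and no level of any gene is reported. The results below concern the gene annotation in the same table, which belongs to no sample and bears on how expression values of the genes under study can be read.

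The table listed 61241 rows, of which 60624 carried an Ensembl gene identifier and 617 carried a serial identifier for a locus without a gene name. Protein-coding genes made up 19605 rows, and 13173 rows carried the general type pseudogene. No gene type was given for 8890 rows, which comprised 8273 Ensembl genes and the 617 unnamed loci. Of the Ensembl identifiers, 58437 were present in GENCODE release 29, and all of these were on the same chromosome in both annotations. Start and end were both equal to GENCODE 29 for 45606 of the matched genes, or 78.0%. Of the 1161 entries in the 43 gene lists fixed before the data were examined, 1160 had a row in the table.

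The genes that encode the constant regions of the IgG heavy chains were listed on chromosome 14, and lie on its reverse strand in GENCODE 29. IGHG4 (ENSG00000211892) lay at 105620506 to 105626066, IGHG2 (ENSG00000211893) at 105639559 to 105644790, IGHG1 (ENSG00000211896) at 105736343 to 105743071 and IGHG3 (ENSG00000211897) at 105764503 to 105771405. IGKC (ENSG00000211592), the kappa light chain constant gene, lay on chromosome 2 at 88857161 to 88857683, also on the reverse strand in GENCODE 29. The positions of these 5 genes were equal to those in GENCODE 29 on GRCh38. The IgG heavy chain genes shared sequence with one another. Among the distinct stretches of 100 bases in the annotated transcripts of IGHG1, 837 of 2758, or 30.3%, also occurred in a transcript of a gene that does not overlap it. All of these were in IGHG2, IGHG3 or IGHG4. The share was 20.1% for IGHG2, 21.2% for IGHG3 and 12.2% for IGHG4, and the partners of these genes also included the pseudogene IGHGP. IGHG2 and IGHG4 each had 65 exon bases in common with a microRNA gene on the opposite strand, MIR8071-2 and MIR8071-1 respectively. The shares of stretches depended on the length of the stretch. For IGHG1 the share was 54.4% with 50 bases and 15.7% with 150 bases, and for IGHG4 it was 42.3% and 4.32%. None of the 424 stretches of IGKC was found elsewhere. A read that lies wholly within a shared stretch has no single origin within the IgG family. How many reads would do so depends on a read length that is not given in the sources used here. Stretches that are similar but not identical were not counted.

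MET (ENSG00000105976), which encodes the c-Met receptor tyrosine kinase, was listed on chromosome 7 at 116672196 to 116798386. SOX2 (ENSG00000181449), a transcription factor of stem and squamous progenitor cells, was listed on the forward strand of chromosome 3 at 181711925 to 181714436. Neither gene had exon bases in common with another annotated gene, and none of the 7257 stretches of 100 bases in MET or the 2414 in SOX2 occurred in a gene at another locus. With stretches of 50 bases the share was 0.252% for MET and 2.03% for SOX2. The integrin genes ITGB4 (chromosome 17) and ITGA6 (chromosome 2), the focal adhesion kinase gene PTK2 (chromosome 8) and SRC (chromosome 20) likewise had no stretch of 100 bases in a gene elsewhere. ITGA6 had 351 of its 6533 merged exon bases, or 5.37%, in common with genes on the opposite strand, among them ITGA6-AS1.

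Among the stemness genes, POU5F1 and NANOG had shared stretches of 100 bases. POU5F1, which encodes the pluripotency factor OCT4, had 11.5% of its 3026 stretches of 100 bases in its copies POU5F1B, POU5F1P3 and POU5F1P4, with 32.2% of stretches of 50 bases and 1.81% of stretches of 150 bases found in genes elsewhere. Of its exons, 8.56% of the merged bases overlapped TCF19 on the opposite strand. NANOG, another pluripotency factor, had 10.5% of its 5486 stretches of 100 bases in genes elsewhere, among them the pseudogenes NANOGP1, NANOGP7 and NANOGP8, against 16.8% with 50 bases and 9.48% with 150 bases. At 50 bases the partners of both genes included many genes that are not their copies, such as HIF1A for POU5F1 and CD96 for NANOG. No stretch of 50, 100 or 150 bases was found elsewhere for PROM1, which encodes the surface protein CD133, for the hyaluronan receptor gene CD44 or for the aldehyde dehydrogenase gene ALDH1A1. Overlap with exons of another gene was 2.23% of merged exon bases for PROM1, on the same strand as FGFBP2, and 0.84% for CD44, on the strand opposite CD44-AS1. The sialyltransferase genes ST3GAL4 and ST6GAL1 had neither shared stretches of these lengths nor overlapping exons.

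The table gave one length for each gene. Fragments per kilobase require such a length as divisor, and whether the listed one was used was not tested. For the 22480 matched genes with more than 1 transcript, the listed length was compared with 5 lengths computed from GENCODE 29. It lay within 1% of the mean length of the gene's transcripts for 14612 genes, or 65.0% (95% Wilson interval 64.4 to 65.6). The share was 35.5% when equality after rounding down was required. With only the basic transcripts of GENCODE 29 it was 14.8%, taken over genes with more than 1 basic transcript. Among multi-transcript genes with the same start and end in both annotations it was 81.6%. For the 35957 matched genes with 1 transcript all 5 computed lengths coincide, and the listed length equalled the transcript for 33094, or 92.0%. The remaining 1-transcript genes thus differed between the annotations whatever the length rule. Of the 16 genes named beforehand that have more than 1 transcript, 13 matched the mean transcript length. The others were MET, with a listed length of 2639 bases against a mean transcript length of 2319 bases, ITGA6 with 2311 against 2276 bases, and POU5F1 with 1261 against 1186 bases. The listed positions of MET and ITGA6 also differed from GENCODE 29 at one end, while those of POU5F1 were the same. Over the 22480 genes, the listed length lay within 1% of the median transcript length for 16.4% and of the longest transcript for 1.24%. It lay within 1% of the shortest for 0.992% and of the merged length of all exons for 0.609%. Mean and median are the same number for the 4664 genes with 2 transcripts, so their matches count for both. Among the 17816 genes with 3 or more transcripts, the listed length matched the mean for 64.4% and the median for 3.08%. The median ratio of the listed length to the mean transcript length was 0.9998, with quartiles of 0.9976 and 1.0032.

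The merged exon length exceeded the listed length by a median factor of 2.41 over these 22480 genes, with quartiles of 1.67 and 3.62. It was at least 2 times the listed length for 13868 genes, or 61.7%. The median factor was 1.42 for genes with 2 transcripts, 2.04 for genes with 3 to 5, 2.99 for genes with 6 to 10 and 4.50 for genes with 11 or more. MET was listed with a length of 2639 bases against a longest transcript of 6635 bases and merged exons of 7039 bases, a factor of 2.67. PTK2 was listed at 1359 bases against 13742 bases of merged exons, a factor of 10.1, and CD44 at 1074 against 10004 bases, a factor of 9.31. Their merged exons pool 57 and 39 annotated transcripts, of which the longest had 4955 bases for PTK2 and 5732 bases for CD44. ST6GAL1 had a factor of 6.97 and PROM1 of 4.32. SOX2, which has a single annotated transcript, was listed at 2512 bases against 2513, and IGKC at 523 bases in both annotations. The IgG heavy chain genes had factors of 1.74 for IGHG1, 1.48 for IGHG2, 1.44 for IGHG3 and 1.47 for IGHG4.

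**Figure D1:**
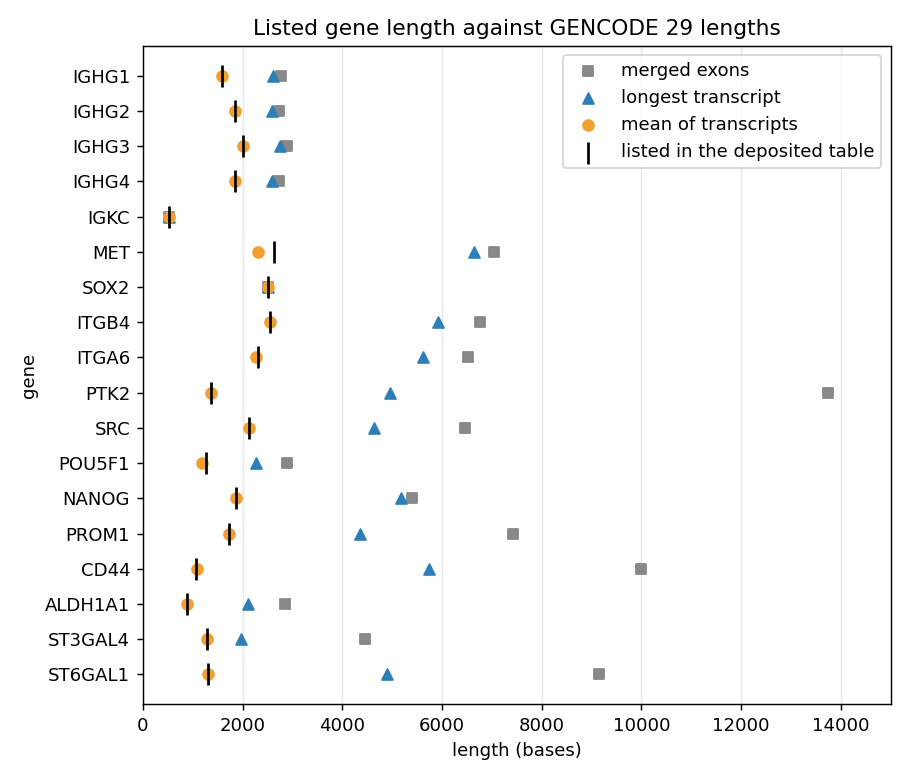
Length in bases (horizontal axis, linear) of the 18 genes named before the data were examined (vertical axis): black bars show the length listed in the deposited table, circles the mean transcript length, triangles the longest transcript and squares the merged exons in GENCODE 29. The listed length sits near the mean transcript length for most of these genes, with MET, ITGA6 and POU5F1 more than 1% apart, and the merged exons reach 13742 bases for PTK2 against a listed 1359.

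The gap differed between gene groups, with no adjustment for the number of transcripts per gene. Across the 42 fixed lists with at least 1 multi-transcript member, the median factor ranged from 1.21 for the immunoglobulin constant genes to 4.19 for the housekeeping controls. The median over all multi-transcript genes was 2.41. Among the lists, it was 3.80 for cytosolic ribosomal proteins, 3.59 for integrins, laminin-332 and focal adhesion genes, and 3.34 for sialyltransferases and sialic acid metabolism. It was 3.16 for the c-Met receptor and its proximal signaling, 2.36 for pluripotency and lung cancer stem cell markers, and 1.70 for squamous differentiation genes. These medians leave out members with a single transcript. Factors within lists spread widely, from 1.12 to 2.17 for the immunoglobulin constant genes and from 1.59 to 5.985 for the housekeeping controls. A length used as a fixed divisor cancels when the same gene is compared between samples. It would not cancel when different genes are ranked by their level, such as an IgG heavy chain gene against a housekeeping gene. The IgG heavy chain genes themselves had factors from 1.44 for IGHG3 to 1.74 for IGHG1, above the median of their list.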

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

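All alternatives given here were chosen after the table had been seen. Those planned beforehand concern the comparison of high and low SIA-cIgG and were not run, because the value columns were not matched to samples. No paired analysis was possible because the columns carry no replicate number of the labels. The share of multi-transcript genes whose listed length matched the mean transcript length, 65.0%, was 35.5% when equality after rounding down was required, 66.6% for protein-coding genes, 81.6% for genes with the same start and end as GENCODE 29, and 14.8% when only the basic transcripts of GENCODE 29 were used. The median factor from listed to merged exon length, 2.41, was 2.69 for protein-coding genes and 2.39 for genes with the same start and end. With basic transcripts it was 1.986, again over the genes with several basic transcripts. With stretches of 50 bases the share found in genes elsewhere was 54.4% for IGHG1, 47.0% for IGHG2, 45.8% for IGHG3, 42.3% for IGHG4, 32.2% for POU5F1 and 16.8% for NANOG. With stretches of 150 bases it was 15.7%, 11.2%, 10.2%, 4.32%, 1.81% and 9.48%, in that order.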

Other observations

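One point chosen after seeing the table concerns its length column. If the listed length was the divisor and reads were counted over all exons of a gene, as a hypothesis that was not tested on the expression values, a gene's FPKM may be higher than one based on merged exons by the factor between both lengths. That factor had a median of 2.69 among protein-coding genes with more than 1 transcript, and was 10.1 for PTK2 and 1.00 for SOX2. Such a factor is the same in every sample, so it would leave the fold change of a gene between high and low SIA-cIgG cells as it is, apart from any pseudocount or minimum level applied to FPKM.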
